A study of Homo sapiens with 76 samples.

How the data were processed

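Total RNA from 76 samples of human subcutaneous adipose tissue was sequenced after depletion of ribosomal RNA, with a strand-specific protocol per the labels' protocols. The frozen tissue was disrupted with ceramic beads, and the RNA was purified on columns with DNase treatment, per the same source. The labels place every sample in a single group and give no measurement of insulin resistance or of any other trait per sample. No groups were therefore compared, and no groups were formed from the values.

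Per the submitters' processing notes, adapters were removed with cutadapt 2.10, reads were aligned with STAR 2.7.8a to the GRCh38.p13 human genome, and reads per gene were counted with featureCounts 2.0.2. The release of the gene annotation and any filter on genes are not given in the labels. The deposited table holds a scaled signal per gene and sample, which was read as CPM, the reads of a gene over an effective library size. It has 19412 genes, of which 19381 have a symbol and 31 have none. The design had assumed plain CPM, which would sum to the same total in each sample, but the columns sum to between 907694 and 1164737. Within each sample, 100% of the values were whole multiples of a single step, with a tolerance of 1e-06, so that whole reads could be recovered by dividing by it. Factors of the trimmed mean of M values (TMM), computed with edgeR on the recovered reads, gave the same effective library sizes within a relative difference of 1.09e-09. The deposited values are thus CPM scaled by TMM, and they are called CPM here.

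The recovered reads per sample numbered 15828060 to 35208500, and 17150 to 17726 genes had a read in a sample. Over genes, a median of 5.36% of the variance between samples was at the level that counting reads alone would give. No pair among the 2850 pairs of samples was close enough to be a repeated library: the smallest mean chi-square per gene between a pair was 22.3. There were 3 copies of genes on the pseudoautosomal region of Y, which were left out, and 110 genes had no read in any sample. Tests used the 14470 genes with a mean of at least 1 CPM, on log2(CPM + 1). Positions, transcript length and GC content came from a GENCODE annotation of GRCh38, and GC content was matched for 99.6% of genes.

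The gene lists, the 3 indices, the 8 list pairs given in full, the tests and the rule for naming genes were fixed before the data were examined. A list score was the mean of its members' z-scored log2(CPM + 1). A minimum of 5 members past the filter for a list to be tested was chosen after the data were seen, and it left 32 lists. For each index, limma 3.58.1 in R 4.3.3 fitted log2(CPM + 1) of every gene on the z-scored index, with a trended prior variance, and p-values were adjusted with the Benjamini-Hochberg method (BH) at 5%. Slopes are therefore in log2(CPM + 1) per SD of the index, a scale that understates changes in genes of low level. Index members were left out of each count. Gene lists were compared with the other genes by camera, with a preset correlation of 0.01 between genes and again with a correlation estimated from the data. Relations of list scores used Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, for which 1e-05 is the smallest p they can give. BH adjustment covered all 496 pairs of lists, for r and for rho separately. Each r was computed again without the 2 samples farthest from the median of the first score, which for pairs other than the 8 is the list that comes first in the fixed order of lists. For variability, the SD of each gene was set against a lowess trend on its mean, with a fraction of 0.2. The median residual of a list was compared with 10000 random lists of the same size drawn from 20 bins of mean expression. Principal components were computed on the centred values.

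Named genes were the 15 with the highest median level with LEP and ADIPOQ, and the 20 most and 10 least variable genes. Those were ranked by the median absolute deviation set against its trend on mean level. For each index they were the 12 genes with the most positive and the 12 with the most negative limma statistic. In each list called by camera, 2 to 4 of the 4 members with the largest statistic were named, and in some lists that were not called a single such member. A mean of at least 5 CPM was required for the variable and index genes. Genes whose level differs by sex, or is known to be set by a common deletion or variant, were left out of the named genes beforehand. A gene that the rule took for the lipogenesis index is not reported here. Other genes named were chosen after their values were seen, and this is said where they appear.

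The alternatives fixed beforehand were a pseudocount of 0.25 in place of 1, no filter, TMM factors computed again, and CPM computed without the mitochondrially encoded and the 10 most abundant genes. Others were the adipocyte score as covariate, the mitochondrially encoded, immediate early and erythroid scores as covariates, and leaving out the 2 farthest samples. For gene counts, edgeR 4.0.16 quasi-likelihood tests were run on the recovered reads. For scores and variability, medians replaced means and the median absolute deviation replaced the SD. Added after the data were seen were CPM without TMM factors, the GC slope of each sample or the erythroid score as covariate, and leaving out the 8 samples highest in the erythroid score. The relation of scores given depth or given GC slope was added then too. The GC slope is the slope, within a sample, of the gene values on transcript GC content. Each index was also permuted over the samples 100 times.

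The tests were tested on simulated data. Counts were drawn for each gene separately from its mean level and dispersion, and some genes were given slopes of 0.1, 0.2 or 0.4 on a random index. Of these, 42.4%, 86.6% and 97.0% were recovered in the right direction, with 6 false calls among 157. Simulated genes did not co-vary, as real ones do, and permuted indices on the real data gave up to 2545 calls. The rate of false calls therefore does not carry over to the real data. A simulated relation of r = 0.5 between a pair of list scores was found in 65% of 20 trials, and 0.02% of 9900 unrelated pairs were called. These trials used fewer resamples and held a single related pair each, whereas 126 positive and 112 negative pairs were called in the real data. BH adjustment is less strict where more pairs are called, so the 65% does not carry over to the real data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.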

Results

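RNA was sequenced from 76 samples of human subcutaneous adipose tissue, the fat layer under the skin, collected from people with obesity and pre-diabetes. The study asks how this tissue's transcriptome relates to insulin resistance, but the labels hold no such measure for any sample. All samples form a single group, so what follows describes levels, spread between samples, and relations between expression values, not relations with insulin resistance. Recovered reads per sample numbered 15828060 to 35208500, and 17150 to 17726 genes had a read in a sample. The labels do not state that each sample came from a different person. The p-values treat the 76 samples as independent, and could be too small if persons were repeated.

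The most abundant transcript came from PLIN4 (ENSG00000167676), which encodes a coat protein of lipid droplets, on chromosome 19 from 4502180 to 4518465 (GRCh38). Its median level was 13113 CPM, with quartiles of 10562 and 15558 CPM (n = 76). AHNAK, a large scaffold protein, followed with a median of 12200 CPM, and the mitochondrially encoded cytochrome oxidase subunit MT-CO1 with 11314 CPM. Others among the 15 most abundant were the lipoprotein receptor LRP1 (6853 CPM), the adhesion protein TNS1 (5444 CPM), the spectrin SPTBN1 (5389 CPM), the matrix proteins SPARC (4832 CPM) and HSPG2 (4123 CPM), and the droplet protein PLIN1 (4237 CPM). The remaining ones were MT-ND4 (4085 CPM), MT-ND5 (3891 CPM), MT-CO3 (3745 CPM) and the translation factor EEF1A1 (3866 CPM), together with SCD and HBB. SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834), the desaturase that makes monounsaturated fatty acids, had a median of 4666 CPM and ranged 147-fold over the samples, from 146 to 21454 CPM. HBB (ENSG00000244734, chromosome 11, 5225464 to 5229395), a subunit of haemoglobin, had a median of 4277 CPM and ranged 164-fold, from 253 to 41348 CPM. The satiety hormone LEP (ENSG00000174697, chromosome 7, 128241284 to 128257628) had a median of 1248 CPM with quartiles of 1070 and 1581 CPM. ADIPOQ (ENSG00000181092, chromosome 3, 186842690 to 186858463), which encodes the hormone adiponectin, had a median of 1074 CPM with quartiles of 884 and 1255 CPM.

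Shares of the total signal show what each cell type's marker list contributed. The 13 adipocyte genes took a median of 2.66% of the total (range 1.59% to 4.07%) and the list for de novo lipogenesis, the making of fatty acids from sugar, 1.06% (0.418% to 3.09%). Extracellular matrix genes took 1.73%, vascular endothelium 0.452%, stromal progenitor markers 0.311%, macrophage markers 0.0993% (0.0448% to 0.195%) and lipid-associated macrophage markers 0.0652%. Markers of T and NK cells took 0.0075%. The erythroid list, made of genes of red blood cells, took a median of 0.476% but ranged from 0.024% to 4.76%. Lists with fewer than 5 members past the filter were not tested. Their summed medians were 78.6 CPM for Schwann cells, 6.34 CPM for mesothelium, 15.5 CPM for keratinocytes and 325 CPM for skeletal muscle, of which the muscle protein gene TTN made up 282 CPM.

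Variability asked which gene groups differ most between samples, given their level. Erythroid genes differed most: their median residual SD was 1.42 on the log2 scale above that of genes of the same level. Markers of neutrophils and monocytes followed (0.91), then lipid-associated macrophages (0.57), T and NK cells (0.41), macrophages (0.32), immediate early genes of the acute stress response (0.31), de novo lipogenesis (0.30) and inflammatory cytokines (0.29). For each of these 8 lists the adjusted p was 0.0008. In all, 20 of 32 lists were more variable than random lists of matched level and 11 were not called, among them the adipocyte list (0.06, adjusted p = 0.118). Ribosomal proteins were the single list that was less variable (-0.06, adjusted p = 0.0433), a call that was lost without the filter on low genes. Random lists hold genes drawn separately, whereas members of a list can co-vary, which makes these p-values too small. The correlation between members that camera estimated in the macrophage fit was 0.905 for erythroid and 0.921 for neutrophil and monocyte genes, against 0.0375 for lymphatic endothelium. Variability was not tested again with such a correlation. The most variable named gene was SCUBE1 (ENSG00000159307), a secreted glycoprotein with EGF-like repeats, whose 10th to 90th percentiles were 1.38 and 52.4 CPM, a ratio of 38. Of the 20 most variable genes, ALAS2, SLC4A1, HBA1, HBA2 and HBB are members of the erythroid list, which in part fixes their r of 0.941 to 0.983 with its score. TENT5C, HEMGN and TRIM58, which are not in the list, had r of 0.971, 0.912 and 0.966 with it. FCGR3B, IL7R and TREM1, genes of white blood cells, had r of 0.766, 0.808 and 0.765 with that score. FOSB, an immediate early transcription factor, spanned a ratio of 27.3 and had r = 0.884 with its own list. SAA2, an acute-phase apolipoprotein (ratio 10.3), COL6A6, a collagen VI chain (14.4), SPX, the gene of the hormone spexin (14.6), CCDC144A (71.8), KLHDC7A (29.6), COMP, a cartilage matrix protein (23.1), and PKP2, a desmosome protein (16.2), had r with the erythroid score between -0.198 and 0.179. HBA1 and HBA2 are near-identical, as are SAA1 and SAA2, so reads may be split between them unevenly. The 10 least variable genes, given their level, were JAK1, NCOR1, CHD8, CELF1, VPS26C, IST1, AHNAK, EEF1A1, MACF1 and SON, with percentile ratios from 1.10 to 1.38.

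**Figure D1:**
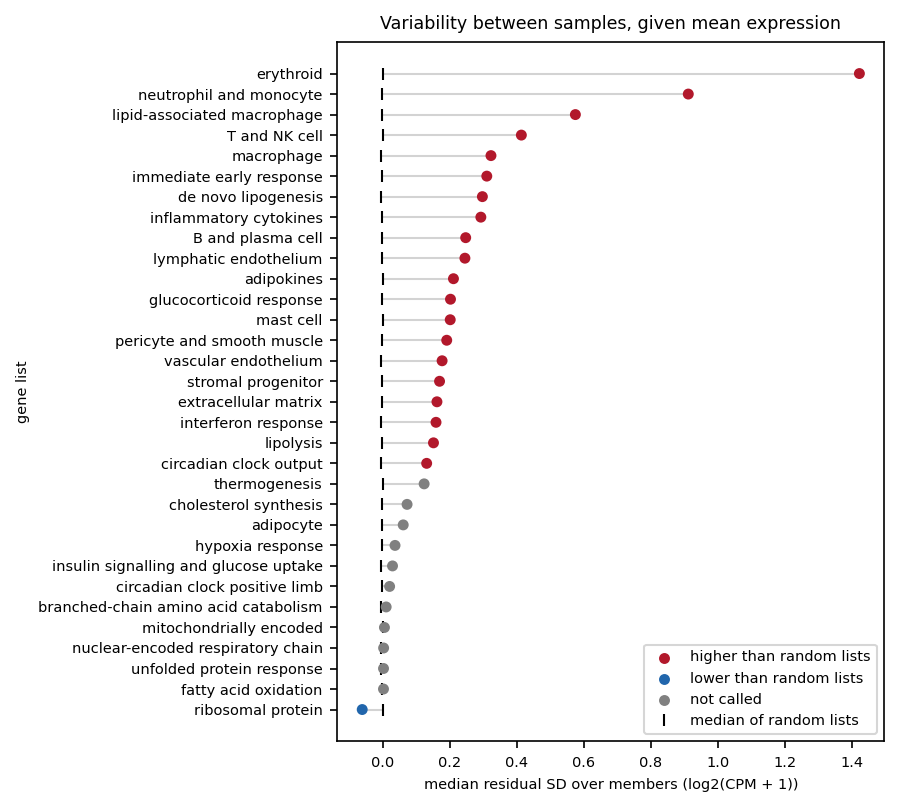
Median residual SD of log2(CPM + 1) for each of the 32 gene lists over 76 samples, with a tick at the median of the random lists of matched level. Red points are lists called more variable, blue less variable and grey not called; the erythroid list stands highest at 1.42.

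The macrophage index, the mean of 13 macrophage marker genes, was used to ask which other genes vary with macrophage content. VSIG4 (ENSG00000155659), a complement receptor, rose by 0.58 ± 0.021 (slope ± SE in log2(CPM + 1) per SD of the index, n = 76), which is 1.5-fold, with an adjusted p of 7.44e-38 by limma and BH. The other 11 genes with the most positive statistic had slopes from 0.29 to 0.56: the folate receptor FOLR2 (0.56), the lectin SIGLEC1 (0.55), the potassium channel KCNJ5 (0.55), the complement receptor C3AR1 (0.54), the transporters SLCO2B1 (0.51) and SLC37A2 (0.44), the G protein GNA15 (0.40), the pore-forming MPEG1 (0.34), the lysosomal FUCA1 (0.33) and CTSZ (0.29), and CD4 (0.32). KLHL23 had the most negative statistic, with a slope of -0.24 ± 0.032 (adjusted p = 1.2e-08). Also lower were the mineralocorticoid receptor NR3C2 (-0.13), the nuclear envelope protein SYNE2 (-0.21), the kinase SNRK (-0.15), the endothelial MYCT1 (-0.24), the mitochondrial deacylase SIRT5 (-0.11) and LNX2 (-0.14). TTC19, FAM120B, EPB41L4A, GPM6B and C1orf21 had slopes from -0.20 to -0.08. Of 14457 genes tested, 2523 rose and 2312 fell with the index, 33.4% in all, and 6268 had an unadjusted p under 0.05. Most slopes were small: the median size among called genes was 0.10, and 182 were beyond 0.3. The index had r = -0.161 with the erythroid score, 0.00969 with the adipocyte score and 0.242 with the GC slope of the samples.

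Lipid-associated macrophage markers, the genes of macrophages that take up fat, rose together with the macrophage index. Of 11 members 10 rose, also 10 adjusted over the list alone, among them the phosphatase ACP5 (0.64 ± 0.061), the lipid receptor TREM2 (0.58), APOC1 (0.46) and GPNMB (0.37). Camera gave an adjusted p of 7.9e-09, and an adjusted p of 0.201 with an estimated correlation. Extracellular matrix genes rose in 12 of 16 cases (12 adjusted over the list alone), such as the protease inhibitor TIMP1 (0.30 ± 0.038) and the collagens COL1A2 (0.20), COL5A1 (0.20) and COL6A3 (0.17), with an adjusted p of 6.66e-06, and an adjusted p of 0.449 with an estimated correlation. Stromal progenitor markers rose in 7 of 12 cases (8 adjusted over the list alone), including PI16 (0.31), LUM (0.21), FBN1 (0.19) and CLEC3B (0.19), with an adjusted p of 0.00725, and an adjusted p of 0.467 with an estimated correlation. Mast cell markers rose in 7 of 9 cases (8 adjusted over the list alone), among them HPGDS (0.31), CPA3 (0.24) and the tryptase TPSAB1 (0.28), with an adjusted p of 0.00306, and an adjusted p of 0.554 with an estimated correlation. In the unfolded protein response list, 5 of 11 members rose and 1 fell (the same counts adjusted over the list alone), with the chaperones SDF2L1 (0.21), PDIA4 (0.17) and HSPA5 (0.15) highest. Its adjusted p was 0.0396, and its adjusted p was 0.469 with an estimated correlation; the call was also lost under both other scalings and without the 2 farthest samples. The mast cell and stromal calls were lost with the mitochondrial, immediate early and erythroid scores as covariates. Ribosomal proteins rose slightly in 11 of 20 cases (12 adjusted over the list alone; median slope 0.05), for example RPS19 (0.08) and RPL19 (0.08), with an adjusted p of 0.00162, and an adjusted p of 0.798 with an estimated correlation.

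Vascular endothelium markers fell with the macrophage index in 9 of 11 cases (10 adjusted over the list alone). Examples were the angiopoietin receptor TEK (-0.24 ± 0.040), EMCN (-0.18), ROBO4 (-0.18) and the VEGF receptor KDR (-0.17). The adjusted p was 0.000173, and the adjusted p was 0.554 with an estimated correlation. Mitochondrially encoded genes fell in 7 of 13 cases (12 adjusted over the list alone), such as MT-CO3 (-0.14) and MT-ND1 (-0.13), with an adjusted p of 0.00183, and an adjusted p of 0.798 with an estimated correlation. None of the 13 adipocyte genes (camera adjusted p = 0.995), the 16 lipogenesis genes (0.940) or the T and NK cell genes (0.318) was called, and none was adjusted over the list alone. In the lymphatic endothelium list, 3 of 6 members rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.262). Those that rose most were the hyaluronan receptor LYVE1 (0.53 ± 0.050), which resident macrophages also carry, and PDPN (0.28). The glucocorticoid target HIF3A fell (-0.37 ± 0.074) and the chemokine CCL2 rose (0.21 ± 0.055), in lists that were not called. Of the 31 lists, 8 were called with the preset correlation and 0 with an estimated one. Without the mitochondrial and 10 most abundant genes 1695 genes rose and 2052 fell with the index, and without TMM factors 1762 rose and 1284 fell.

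The de novo lipogenesis index, the mean of 16 genes, was used to ask what varies with this insulin-responsive pathway. Besides enzymes that make and desaturate fatty acids, the list held other genes, such as SREBF1, MLXIPL, THRSP, DGAT2 and PNPLA3. GPAM (ENSG00000119927), the first enzyme of glycerolipid synthesis, rose by 0.40 ± 0.036 (slope ± SE in log2(CPM + 1) per SD, n = 76), which is 1.32-fold (adjusted p = 1.09e-13). AGPAT2, the next enzyme (0.36), the phosphatidate phosphatase LPIN1 (0.20), the citrate carrier SLC25A1 (0.35), the pyruvate dehydrogenase subunit DLAT (0.23) and the sterol reductase DHCR7 (0.32) also rose. So did the adenosine receptor ADORA1 (0.40), the fat cell lectin LGALS12 (0.33), FAH (0.26), PDXK (0.24), MMAB (0.16) and EIF4G1 (0.16). The gene with the most negative statistic was C11orf80 (-0.16 ± 0.022, adjusted p = 3.89e-08). Also lower were the transporter ABCC4 (-0.24), DOCK10 (-0.24), the lectin CLEC2D (-0.25), the lymphocyte GTPase GIMAP2 (-0.18) and the leukotriene receptor CYSLTR1 (-0.19), and CCSER1, GPRIN3, INTS6L, N4BP2L1 and PTBP3 with slopes from -0.23 to -0.14. Of 14454 genes tested, 2651 rose and 2218 fell, 33.7% in all, and 6241 had an unadjusted p under 0.05. The index had r = 0.641 with the adipocyte score (rho = 0.633; r = 0.605 without the 2 farthest samples) and -0.347 with the erythroid score. The split between directions depended on the scaling: 1155 genes rose and 3459 fell without the mitochondrial and 10 most abundant genes, a scaling that raised values by a median of 0.157 (log2), and 961 rose and 3966 fell without TMM factors. With the adipocyte score as covariate, 131 genes rose and 25 fell, 121 of these 156 called in the same direction as before, and the 12 genes with the most negative statistic were no longer called.

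**Figure D2:**
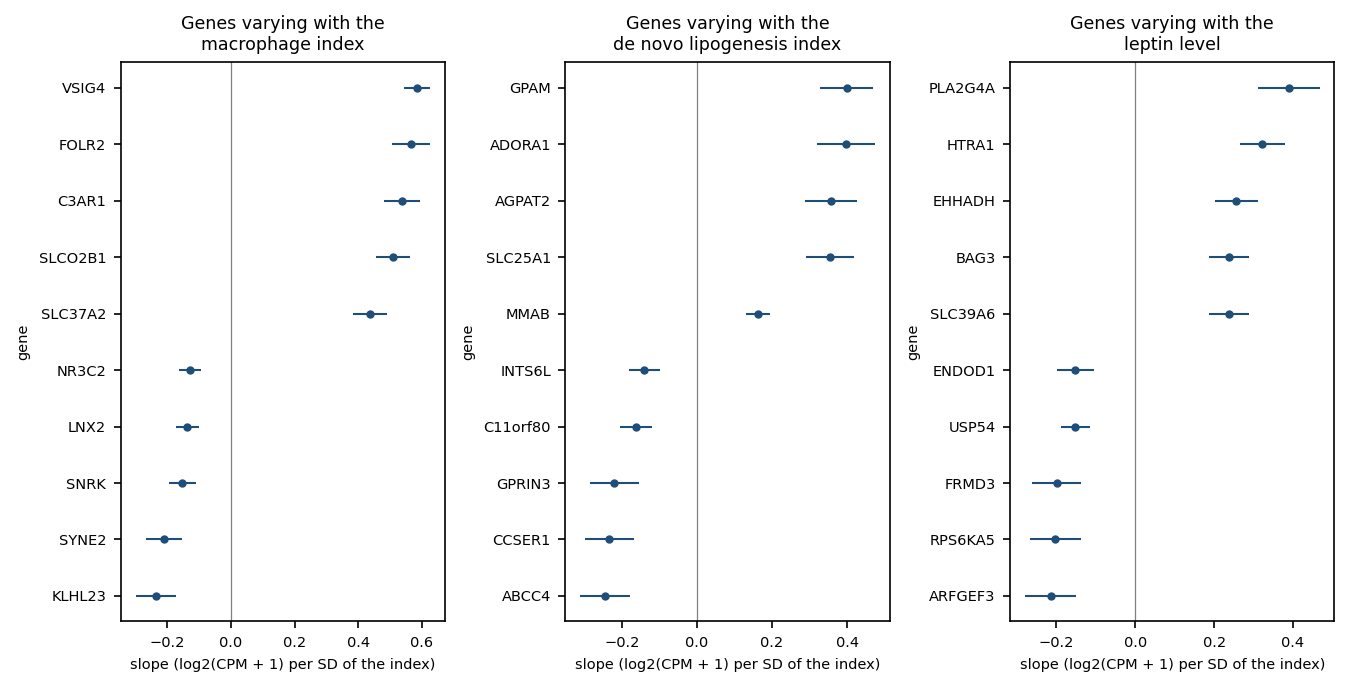
Slopes in log2(CPM + 1) per SD of the macrophage index, the de novo lipogenesis index and the leptin level for the 5 genes with the most positive and the 5 with the most negative statistic of each, over 76 samples. Points are slopes and bars their 95% intervals; VSIG4 is highest on the macrophage index (0.58), GPAM on lipogenesis (0.40) and PLA2G4A on leptin (0.39).

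Every member of the insulin signalling list rose with the lipogenesis index (9 of 9, also 9 adjusted over the list alone). The insulin-responsive glucose transporter SLC2A4 had a slope of 0.43 ± 0.060, the adaptor IRS1 0.32 and the kinase AKT2 0.18. Cholesterol synthesis genes rose in 9 of 14 cases, with 11 up and 1 down adjusted over the list alone, such as the sterol sensor INSIG1 (0.34), DHCR7 (0.32), MVD (0.22) and LSS (0.20). Nuclear-encoded respiratory chain genes rose in 21 of 22 cases (21 adjusted over the list alone), among them ATP5MC3 (0.18), ATP5F1B (0.18) and SDHB (0.13). The adjusted p-values of these 3 lists were 2.4e-07, 3.62e-05 and 8.43e-16, and each was 0.0477 with an estimated correlation. Adipocyte genes rose in 11 of 13 cases (12 adjusted over the list alone), including the droplet protein CIDEC (0.29), PLIN4 (0.28), the transcription factor CEBPA (0.27) and GPD1 (0.24), with an adjusted p of 6.77e-09, and an adjusted p of 0.0596 with an estimated correlation. Lipolysis genes rose in 8 of 12 cases (8 adjusted over the list alone), with the lipases PNPLA2 (0.24) and LIPE (0.24) and the lipase inhibitor G0S2 (0.23) among them. The adjusted p was 0.000271, and the adjusted p was 0.211 with an estimated correlation. Fatty acid oxidation genes rose in 8 of 11 cases (9 adjusted over the list alone), such as HADH (0.20) and ECI1 (0.16), with an adjusted p of 0.000187, and an adjusted p of 0.236 with an estimated correlation. Branched-chain amino acid catabolism genes rose in 9 of 16 cases (12 adjusted over the list alone), led by PCCB (0.16) and MCCC1 (0.13), with an adjusted p of 0.000243, and an adjusted p of 0.283 with an estimated correlation. With the adipocyte score as covariate, the insulin signalling, adipocyte and fatty acid oxidation lists were no longer called, and the median slopes of lipolysis and branched-chain catabolism turned to -0.01 and -0.03. For the adipocyte list this was largely fixed in advance, since its own score was the covariate.

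Adipokines rose with the lipogenesis index in 4 of 7 cases (4 adjusted over the list alone), among them RARRES2 (0.28), RBP4 (0.24) and CFD (0.20), with an adjusted p of 0.0302, and an adjusted p of 0.283 with an estimated correlation. Clock output genes rose in 5 of 10 cases (5 adjusted over the list alone), such as CRY2 (0.14) and TEF (0.14), with an adjusted p of 0.0189, and an adjusted p of 0.467 with an estimated correlation. Unfolded protein response genes rose in 5 of 11 cases (5 adjusted over the list alone), led by ATF4 (0.11) and DDIT3 (0.09), with an adjusted p of 0.0361, and an adjusted p of 0.283 with an estimated correlation. Mitochondrially encoded genes rose in 6 of 13 cases (6 adjusted over the list alone), led by MT-CYB (0.12) and MT-CO2 (0.12), with an adjusted p of 0.00637, and an adjusted p of 0.571 with an estimated correlation. The adipokine and clock output lists were no longer called with the adipocyte score as covariate. Of the ribosomal proteins, 3 of 20 were called with a positive slope (2 adjusted over the list alone), RPLP0 (0.08) and RPL4 (0.06) first, but the list's median slope of 0.03 turned to -0.01 without the mitochondrial and most abundant genes and to -0.02 without TMM factors (adjusted p of 0.601 and 0.846), and to -0.02 with the adipocyte score as covariate (adjusted p = 0.0125). Both scalings shift the other genes too, so no direction is given for this list. Their adjusted p was 0.0361, and it was an adjusted p of 0.658 with an estimated correlation.

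Genes of white and red blood cells fell with the lipogenesis index. All 13 T and NK cell genes fell (13 adjusted over the list alone), including IL7R (-0.47 ± 0.106), the adhesion receptor CD2 (-0.31) and the T cell receptor chain CD3G (-0.31), with an adjusted p of 1.19e-06, and an adjusted p of 0.283 with an estimated correlation. All 8 neutrophil and monocyte genes fell (8 adjusted over the list alone), such as S100A12 (-0.25) and the calprotectin subunit S100A8 (-0.39), with an adjusted p of 0.0034, and an adjusted p of 0.467 with an estimated correlation. B and plasma cell genes fell in 5 of 7 cases (6 adjusted over the list alone), with MS4A1, which encodes CD20, at -0.39 and POU2AF1 at -0.24, an adjusted p of 0.00869, and an adjusted p of 0.294 with an estimated correlation. Erythroid genes fell in 6 of 7 cases (7 adjusted over the list alone), such as SLC4A1 (-0.61) and HBB (-0.56), with an adjusted p of 0.00259, and an adjusted p of 0.448 with an estimated correlation. The scores of the T and NK, neutrophil and B cell lists had r of 0.790, 0.777 and 0.700 with the erythroid score (rho of 0.775, 0.782 and 0.659, each permutation p = 1e-05, adjusted p = 7.19e-05 for r and 8.86e-05 for rho; r of 0.771, 0.757 and 0.662 without the 2 farthest samples). Vascular endothelium genes fell in 5 of 11 cases (6 adjusted over the list alone), led by PECAM1 (-0.16) and TEK (-0.17), with an adjusted p of 0.0034, and an adjusted p of 0.467 with an estimated correlation. Interferon response genes fell in 5 of 15 cases (5 adjusted over the list alone), such as EPSTI1 (-0.13) and OAS2 (-0.12), with an adjusted p of 0.0203, and an adjusted p of 0.579 with an estimated correlation. With the adipocyte score as covariate, the T and NK, B, neutrophil and erythroid lists were no longer called, and the median slopes of the vascular endothelium and interferon lists turned to 0.01 and 0.04. Macrophage genes were not called (camera adjusted p = 0.970), with 1 of 13 lower, FCGR3A (-0.22), which was also the 1 called adjusted over the list alone. In lists that were not called, the angiogenic factor VEGFA (0.23 ± 0.035) and the adhesion molecule MCAM (0.22 ± 0.027) rose. Their lists were mixed: 4 of 13 hypoxia response genes rose and 3 fell, and 1 of 9 pericyte and smooth muscle genes rose and 3 fell. Of the 31 lists, 18 were called with the preset correlation and 3 of them held with an estimated one.

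The level of LEP was used to ask what varies with leptin, whose expression is known to follow fat cell size. HTRA1 (ENSG00000166033), a secreted protease, rose by 0.32 ± 0.029 (slope ± SE in log2(CPM + 1) per SD of the LEP level, n = 76), which is 1.25-fold (adjusted p = 2.59e-13). PLA2G4A, which releases arachidonic acid from membranes (0.39), the basement membrane collagen COL4A1 (0.20), the peroxisomal enzyme EHHADH (0.26), the phospholipase GPLD1 (0.32), the zinc carrier SLC39A6 (0.24) and SDSL (0.33) also rose. So did the co-chaperone BAG3 (0.24), the proteasome subunit PSMB5 (0.18) and the chaperonin CCT5 (0.16), and SND1 (0.20) and OTUD7B (0.18). USP54 had the most negative statistic (-0.15 ± 0.019, adjusted p = 4.97e-09). SORBS2, an adaptor of the cytoskeleton (-0.29), SULF2, which edits heparan sulfate (-0.24), TBC1D1, a regulator of glucose transporter traffic (-0.14), and the kinase RPS6KA5 (-0.20) were lower as well. ARFGEF3, ENDOD1, FRMD3, KMT2A, RSBN1L, LRRC49 and ZNF394 had slopes from -0.21 to -0.08. Of 14469 genes tested, 2482 rose and 2162 fell, 32.1% in all, and 6185 had an unadjusted p under 0.05. The LEP level had r = 0.404 with the adipocyte score, -0.292 with the erythroid score and 0.361 with log2 depth. Without the mitochondrial and most abundant genes 1218 rose and 2504 fell, and without TMM factors 1225 rose and 2206 fell. With the adipocyte score as covariate 948 rose and 543 fell, and with the erythroid score as covariate 1695 rose and 1311 fell. With the GC slope as covariate 3509 rose and 3327 fell.

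Nuclear-encoded respiratory chain genes rose with LEP in 19 of 22 cases (19 adjusted over the list alone), such as UQCRFS1 (0.16), SDHC (0.15) and ATP5F1A (0.13), with an adjusted p of 3.06e-10, and an adjusted p of 0.414 with an estimated correlation. Lipolysis genes rose in 7 of 12 cases (7 adjusted over the list alone), led by the antilipolytic adrenergic receptor ADRA2A (0.30 ± 0.039) and G0S2 (0.24), with an adjusted p of 0.000898, and an adjusted p of 0.414 with an estimated correlation. Fatty acid oxidation genes rose in 6 of 11 cases (7 adjusted over the list alone), with ACAA2 (0.17) and ACADVL (0.14), an adjusted p of 0.000659, and an adjusted p of 0.415 with an estimated correlation. Adipokines rose in 4 of 6 cases (4 adjusted over the list alone), with RBP4 (0.28) and RARRES2 (0.27), an adjusted p of 0.0201, and an adjusted p of 0.414 with an estimated correlation. Adipocyte genes rose in 7 of 13 cases (10 adjusted over the list alone), such as CEBPA (0.21), PLIN4 (0.20) and LPL (0.19). Macrophage genes rose in 7 of 13 cases (7 adjusted over the list alone), led by the complement genes C1QA (0.28) and C1QB (0.26). Lipogenesis genes rose in 6 of 16 cases (9 adjusted over the list alone), such as ME1 (0.23) and THRSP (0.21), and insulin signalling genes in 5 of 9 (6 adjusted over the list alone), led by IRS1 (0.28) and TBC1D4 (0.07). With the adipocyte score as covariate, the median slopes of the adipocyte and insulin signalling lists turned to -0.0010 and -0.0052. For the adipocyte list the loss of slope was largely fixed in advance, since its own score was the covariate. Matrix genes rose in 6 of 16 cases (6 adjusted over the list alone), among them COL3A1 (0.30), COL5A2 (0.20) and the crosslinking enzyme LOX (0.20). In the branched-chain amino acid list 6 of 16 rose and 1 fell (9 and 1 adjusted over the list alone), with HIBADH at 0.15 and BCKDHA at -0.10. In cholesterol synthesis 5 of 14 rose (5 adjusted over the list alone), such as INSIG1 (0.21) and HMGCS1 (0.11). The adjusted p-values of the last 7 lists were 0.000898, 0.0133, 0.00237, 0.0102, 0.0133, 0.0133 and 0.0377, and the adjusted p with an estimated correlation was 0.584 for macrophage genes and 0.528 for the others. The lipolysis, fatty acid oxidation, lipogenesis, branched-chain and cholesterol lists were no longer called with the adipocyte score as covariate.

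All 8 neutrophil and monocyte genes fell with LEP (8 adjusted over the list alone), with FCGR3B at -0.54 ± 0.149 and CXCR2 at -0.35. T and NK cell genes fell in 5 of 13 cases (6 adjusted over the list alone), such as CD2 (-0.20) and CCL5 (-0.22), B and plasma cell genes in 5 of 7 (5 adjusted over the list alone), such as MS4A1 (-0.34) and CD79B (-0.18), and erythroid genes in 4 of 7 (5 adjusted over the list alone), such as HBA1 (-0.53) and CA1 (-0.36). Vascular endothelium genes fell in 5 of 11 cases (8 adjusted over the list alone), led by TEK (-0.22) and PECAM1 (-0.15), and glucocorticoid response genes in 4 of 9 (5 adjusted over the list alone), led by HIF3A (-0.35) and FKBP5 (-0.22). The adjusted p-values of these 6 lists were 0.00386, 0.00237, 0.0232, 0.0116, 0.00124 and 0.0201, and each was an adjusted p of 0.528 with an estimated correlation. The first 5 of these lists were no longer called with the adipocyte score as covariate. Of the 32 lists, 17 were called with the preset correlation and 0 with an estimated one. Outside the called lists, the stromal SEMA3C rose (0.29 ± 0.041) and the acute-phase gene SAA1 rose (0.46 ± 0.109). In their lists, 1 of 12 stromal progenitor genes rose and 1 fell, and 1 of 10 inflammatory cytokine genes rose and 2 fell (1 and 4 adjusted over the list alone). The ribosomal protein and clock positive limb lists, neither called, had a median of the opposite sign to the test or the mean on LEP, as had fatty acid oxidation, thermogenesis and immediate early genes on macrophage and thermogenesis on lipogenesis. Of the genes called for both lipogenesis and LEP, 1606 rose with both, 1246 fell with both and 0 went opposite ways. For macrophage and lipogenesis, 922 rose with both, 734 fell with both, and 147 and 39 went opposite ways. The indices were fitted on the same samples and genes co-vary, so these overlaps were not tested.

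Relations between list scores asked which cell types and pathways vary together. Matrix genes moved with macrophage genes (r = 0.560, 95% interval 0.383 to 0.697, permutation p = 1e-05, adjusted p = 7.19e-05; rho = 0.555, permutation p = 1e-05, adjusted p = 8.86e-05; r = 0.531 without the 2 farthest samples). Lipogenesis moved with insulin signalling (r = 0.693, 0.553 to 0.794, permutation p = 1e-05, adjusted p = 7.19e-05; rho = 0.678, permutation p = 1e-05, adjusted p = 8.86e-05; r = 0.692 without 2), with a partial r of 0.343 given the adipocyte score. Lipogenesis moved with branched-chain amino acid catabolism (r = 0.482, 0.288 to 0.638, permutation p = 2e-05, adjusted p = 0.000134; rho = 0.520, permutation p = 1e-05, adjusted p = 8.86e-05; r = 0.512 without 2), with a partial r of -0.0383 given the adipocyte score. This relation was no longer past the threshold without TMM factors. Immediate early genes moved with cytokines (r = 0.796, 0.696 to 0.866, permutation p = 1e-05, adjusted p = 7.19e-05; rho = 0.816, permutation p = 1e-05, adjusted p = 8.86e-05; r = 0.783 without 2). Clock output genes opposed the list named for the clock's positive limb (r = -0.531, -0.676 to -0.347, permutation p = 1e-05, adjusted p = 7.19e-05; rho = -0.500, permutation p = 2e-05, adjusted p = 0.000155; r = -0.439 without 2). That list held BMAL1, CLOCK, NPAS2, NFIL3 and CRY1, so it does not stand for the clock's activators alone. Its members differed: with PER3, for example, r was -0.570 for NFIL3, -0.529 for BMAL1, -0.394 for NPAS2, 0.0347 for CRY1 and 0.0017 for CLOCK. Macrophage genes showed no relation past the threshold with lipogenesis (r = 0.0296, -0.197 to 0.253, permutation p = 0.80, adjusted p = 0.850; rho = -0.0226, permutation p = 0.846, adjusted p = 0.891; r = 0.0108 without 2). The same held with adipocyte genes (r = 0.00969, -0.216 to 0.235, permutation p = 0.934, adjusted p = 0.957; rho = -0.0618, permutation p = 0.596, adjusted p = 0.691; r = -0.0361 without 2). It also held with respiratory chain genes (r = 0.207, -0.019 to 0.414, permutation p = 0.0720, adjusted p = 0.124; rho = 0.134, permutation p = 0.246, adjusted p = 0.343; r = 0.143 without 2), although r was 0.278 (adjusted p = 0.0339) with the median of z-scores, 0.382 (adjusted p = 0.00472) given the adipocyte score and 0.326 (adjusted p = 0.0131) given the mitochondrial, immediate early and erythroid scores. Of the 496 pairs, 126 were positive, 112 negative and 258 not called, and all p-values were two-sided. Random lists of matched level also correlated: of 1000 random pairs, 95% lay between -0.481 and 0.523 for the immediate early and cytokine pair, below its r, while the r of macrophage with matrix stood at percentile 83.0, of lipogenesis with insulin signalling at 85.6, with branched-chain catabolism at 85.0 and of the clock pair at 4.4.

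**Figure D3:**
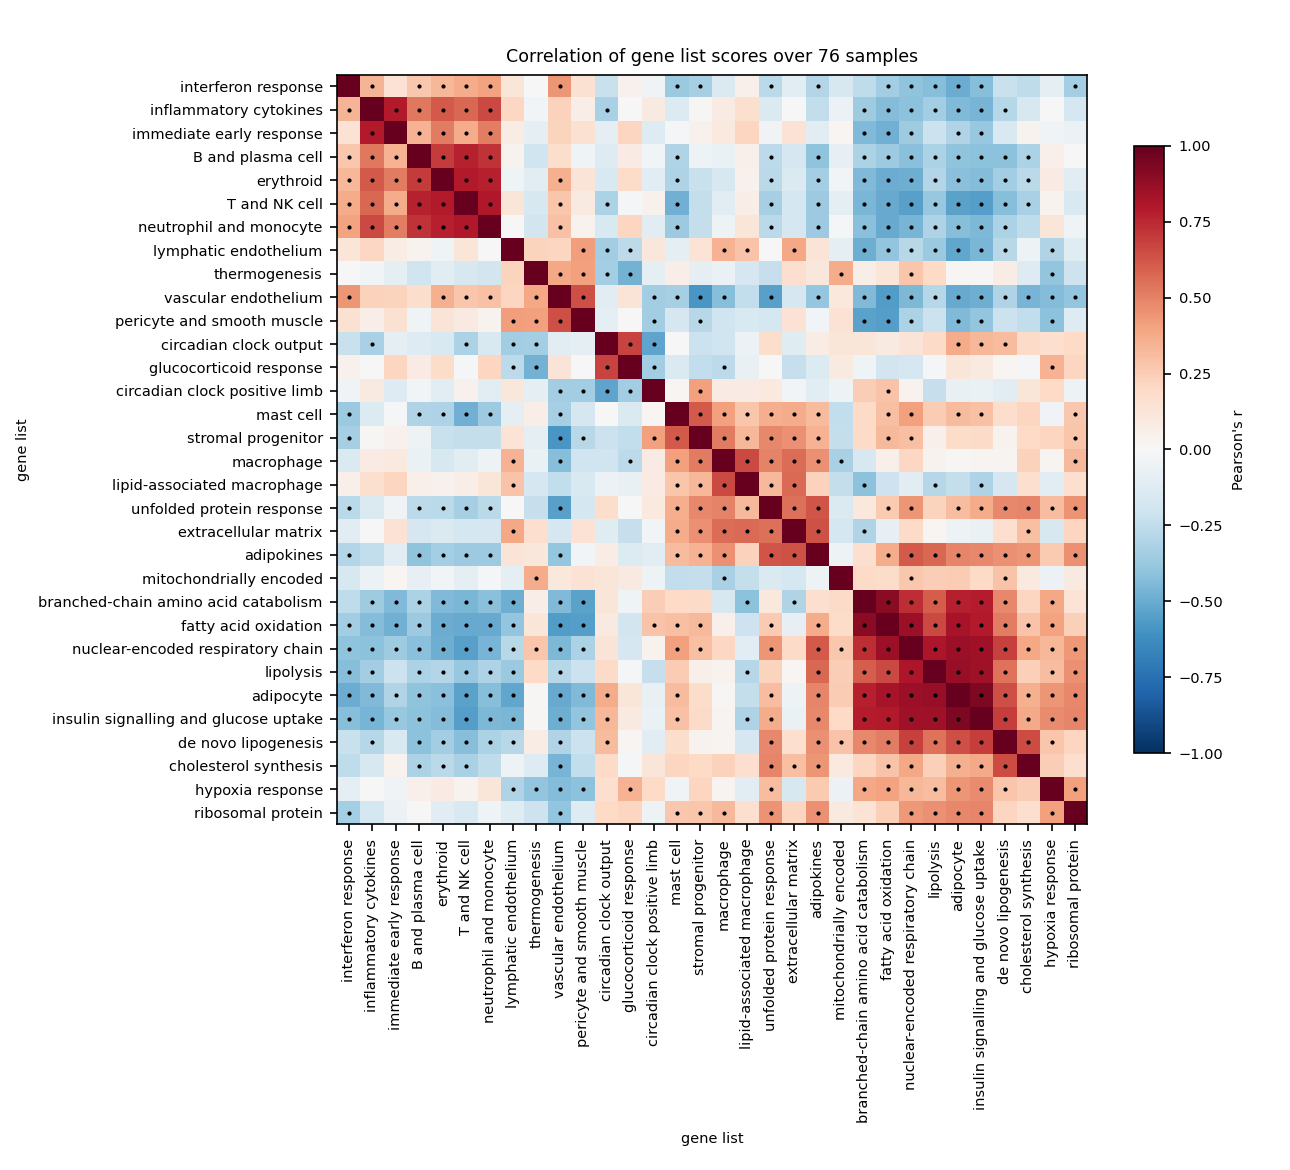
Pearson's r between the scores of the 32 gene lists over 76 samples, in clustered order, with a dot where the adjusted p was under 0.05. Erythroid, T and NK cell, and neutrophil lists form a positive block (r of 0.777 to 0.798), opposite to the adipocyte list (r = -0.421 with erythroid).

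**Figure D4:**
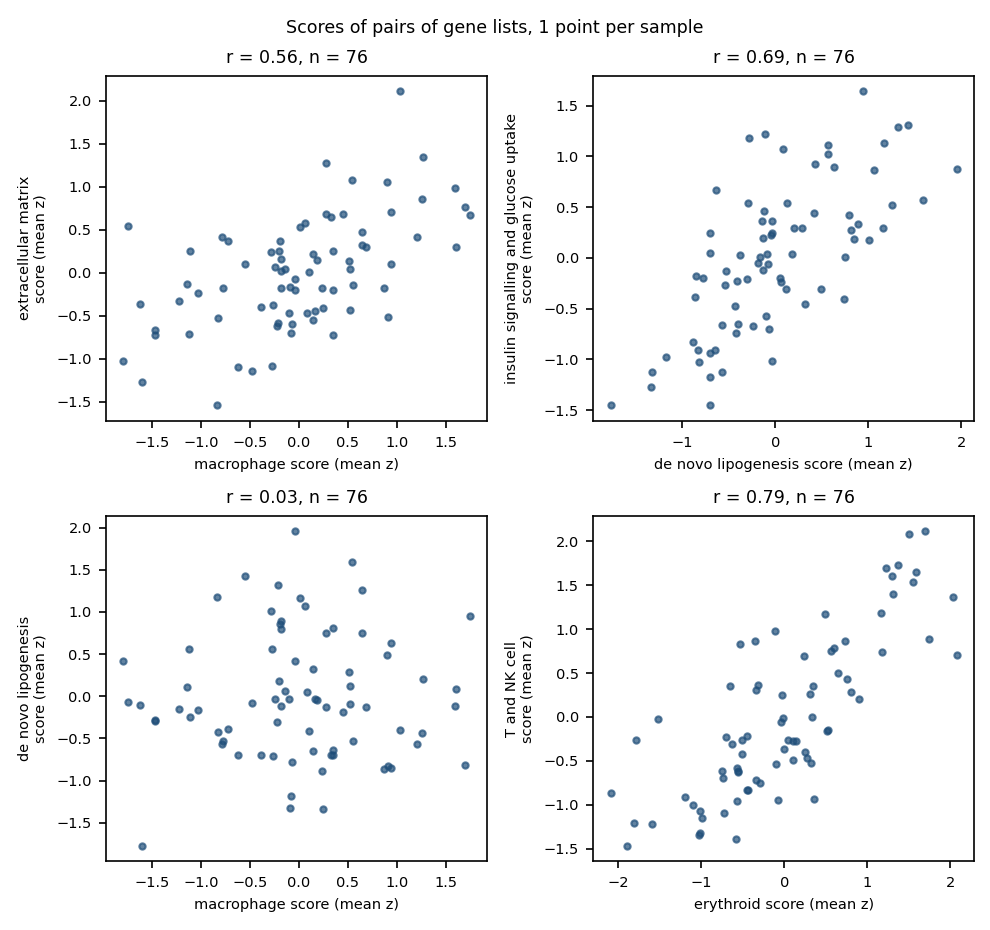
List scores (mean z-score of members) of each of the 76 samples, a point per sample, for 4 pairs of lists. Macrophage rose with extracellular matrix (r = 0.560), lipogenesis with insulin signalling (r = 0.693) and erythroid with T and NK cells (r = 0.790), while macrophage and lipogenesis gave r = 0.0296.

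The first 3 principal components held 21.9%, 15.6% and 8.09% of the variance. Component 1 rose with neutrophil (r = 0.707, rho = 0.637), erythroid (r = 0.685, rho = 0.607) and vascular endothelium genes (r = 0.638, rho = 0.654), and fell with branched-chain amino acid (r = -0.705, rho = -0.662) and fatty acid oxidation genes (r = -0.705, rho = -0.701). Component 2 rose with adipokines (r = 0.779, rho = 0.796) and lipolysis (r = 0.711, rho = 0.646). Component 3 set vascular endothelium (r = 0.666, rho = 0.600) against macrophage (r = -0.655, rho = -0.585) and lipid-associated macrophage genes (r = -0.638, rho = -0.616). For each of these, the permutation p was 1e-05, the adjusted p 4.08e-05 for r and 5.1e-05 for rho, and r without the 2 farthest samples was 0.663, 0.651, 0.640, -0.686, -0.673, 0.781, 0.700, 0.617, -0.675 and -0.614 in the order given. The components were computed from the same expression values, list members included. Of 14442 genes, 5697 had an r beyond 0.5 in size with component 1, 4646 with component 2 and 959 with component 3. The p-values therefore test chance pairing of samples only, and single out no cell type or pathway. The GC slope of the samples had r = 0.756 with component 1 and 0.646 with component 2. No component split the samples into clusters by the Bayesian information criterion, and the labels give no batches.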

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

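Tests without TMM factors, with the GC slope or the erythroid score as covariate, without the 8 samples highest in the erythroid score, and given depth or GC slope were chosen after the results were seen. All 72 genes that the naming rule took for an index kept their direction and call under every alternative run for them, except that with the adipocyte score as covariate 60 did and 12, the negative ones of lipogenesis, lost their call. A pseudocount of 0.25 changed no count of called genes by over 1.5 times, nor did edgeR on the recovered reads, which called 4799, 4932 and 4670 genes for macrophage, lipogenesis and LEP, of which 4651, 4735 and 4485 were shared with limma. Fewer calls were shared in the same direction elsewhere: 3565 of 4835 for macrophage with the GC slope as covariate, 2979 without TMM factors and 3508 without the mitochondrial and most abundant genes. For lipogenesis 3173 of 4869 were shared without TMM factors and 3355 without the mitochondrial and most abundant genes, and for LEP 2977 and 3143 of 4644. Computing TMM factors again moved almost nothing, and neither it nor the absence of a filter, for relations of scores, tests those results. Relations of the preset pairs ranged from 0.492 to 0.561 for macrophage with matrix, 0.343 to 0.698 for lipogenesis with insulin signalling, 0.710 to 0.808 for immediate early genes with cytokines and -0.642 to -0.439 for the clock pair.

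Without the mitochondrial and 10 most abundant genes, lipogenesis had 1155 genes up and 3459 down and LEP 1218 up; ribosomal proteins reversed, to -0.009441 on lipogenesis (adjusted p = 0.601) and -0.03292 on LEP (adjusted p = 0.0415). Without TMM factors, 1284 genes fell with macrophage, 961 rose and 3966 fell with lipogenesis and 1225 rose with LEP, the relation of lipogenesis with branched-chain catabolism was 0.244 (adjusted p = 0.0753), and ribosomal proteins reversed, to -0.01701 on lipogenesis (adjusted p = 0.846) and -0.03337 on LEP (adjusted p = 0.0251). Both scalings move all genes of a sample together, and beyond that the cause was not tested. With no filter, 0 lists were less variable, with more low genes in the comparison. With the adipocyte score as covariate, 131 genes rose and 25 fell with lipogenesis, and 948 rose and 543 fell with LEP. The medians that reversed were, on lipogenesis, vascular endothelium 0.01485, lipolysis -0.00883, branched-chain catabolism -0.02893, interferon response 0.03883 and ribosomal proteins -0.02008 (adjusted p = 0.0125), and on LEP adipocyte -0.001033, insulin signalling -0.005153, interferon response 0.07087 (adjusted p = 0.0109) and ribosomal proteins -0.03501 (adjusted p = 0.000986). The adipocyte list's own score is removed by this covariate, so its loss of slope was largely fixed in advance. Given the adipocyte score, the r of lipogenesis with branched-chain catabolism was -0.03826 (adjusted p = 0.834) and of macrophage with the respiratory chain 0.382 (adjusted p = 0.00472). With the mitochondrial, immediate early and erythroid scores as covariates, 1320 genes fell with lipogenesis and 1372 with LEP, and the macrophage and respiratory chain r was 0.326 (adjusted p = 0.0131). Medians that reversed were mitochondrial genes on macrophage (0.005314) and lipogenesis (-0.000914) and erythroid genes on lipogenesis (0.01088), lists whose own score is then removed, as with the erythroid score alone (0.01627). The median of z-scores gave 0.278 (adjusted p = 0.0339) for macrophage and respiratory chain. For LEP, 3327 genes fell with the GC slope as covariate, 1311 with the erythroid score and 1291 without the 8 samples highest in it. Beside these, of 94 list medians on the indices, calls were lost for 19 and gained for 5 with the adipocyte score, lost for 13 and gained for 1 with the mitochondrial, immediate early and erythroid scores, lost for 11 with the erythroid score and for 4 with the GC slope. Calls were lost for 4 without the mitochondrial and most abundant genes, lost for 2 and gained for 1 without TMM factors, and lost for 2 and gained for 4 without the 2 farthest samples. Except where stated, the cause was not tested. Small slopes were the hardest to find: 42.4% of simulated slopes of 0.1 were recovered, against 97.0% of slopes of 0.4. Counting reads accounted for a median of 5.36% of the variance between samples, so counting noise was a minor limit for most genes. That share does not test depth in other ways. Log2 depth had r = -0.147, 0.319 and -0.260 with components 1, 2 and 3 and 0.361 with the LEP level. The gene fits were not run with depth as covariate.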

Other observations

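Of the tests in this part, those of tissue immune cells, of sequencing depth, of the clock median by rho and without 2 samples, and with the GC slope or the erythroid score as covariate were chosen after the result was seen, as was the choice of the genes and pairs in the first 2 paragraphs that lie outside the naming rule. Among 105 pairs of 15 clock genes over the 76 samples, 47 had a positive and 26 a negative relation past the threshold, and 32 had none. The output genes DBP and TEF, transcription factors driven by the clock, had r = 0.805 (permutation p = 1e-05, adjusted p = 3e-05; rho = 0.815, permutation p = 1e-05; r = 0.80 without the 2 farthest samples). NR1D1, which encodes the repressor REV-ERB alpha, had r = 0.770 with DBP (permutation p = 1e-05, adjusted p = 3e-05; rho = 0.764, permutation p = 1e-05; 0.751 without 2). BMAL1, the activator of the clock, opposed TEF (r = -0.633, permutation p = 1e-05, adjusted p = 3e-05; rho = -0.559, permutation p = 1e-05; -0.589 without 2). Its r with PER2 was -0.421, but -0.191 without the 2 farthest samples (permutation p = 0.00022, adjusted p = 0.000525; rho = -0.208, permutation p = 0.0714), so that relation rests on those samples. Against this pattern, CLOCK, the partner of BMAL1, moved with the output gene NR1D2 (r = 0.639, permutation p = 1e-05, adjusted p = 3e-05; rho = 0.658, permutation p = 1e-05; 0.659 without 2). The clock output score moved with the glucocorticoid response score (r = 0.674, rho = 0.632, 0.642 without 2), and glucocorticoid genes opposed thermogenesis genes (r = -0.475, rho = -0.470, -0.436 without 2). The thermogenesis score held the 8 of 11 list genes past the filter, and camera estimated a correlation of 0.114 between them in the macrophage fit. That score need not stand for a single programme. UCP1, the uncoupling protein of brown fat, had a median of 0.308 CPM with quartiles of 0.246 and 0.425 CPM.

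Cell type markers also moved against each other. Vascular endothelium opposed stromal progenitors (r = -0.581, rho = -0.565, -0.532 without 2) and moved with pericytes (r = 0.646, rho = 0.673, 0.719 without 2). Mast cells moved with stromal progenitors (r = 0.614, rho = 0.583, 0.548 without 2). Adipocyte genes opposed T and NK cell genes (r = -0.535, rho = -0.460, -0.475 without 2). For these and the glucocorticoid pairs, the permutation p was 1e-05 for r and at most 3e-05 for rho, and the adjusted p over 496 pairs was 7.19e-05 for r and at most 0.000213 for rho. These p-values test chance pairing of samples only. Random lists of matched level, which also correlated, were drawn for the preset pairs only. Whether the r of the pairs given here exceed those of random lists was therefore not tested, and they may not be particular to these cell types or pathways. The acute-phase genes SAA1 and SAA2, near-identical paralogs, rose with the LEP level by 0.46 ± 0.109 and 0.64 ± 0.141 (log2(CPM + 1) per SD, limma adjusted p of 0.00082 and 0.000372, n = 76), and SCUBE1 by 0.53 ± 0.180 (adjusted p = 0.0199).

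The samples may have been taken at different phases of the clock. If so, BMAL1 and NPAS2 should oppose the 10 clock output genes, and the median r over these pairs was -0.307, just past the bound of -0.3 set beforehand. The median was -0.218 by Spearman's rho and -0.214 without the 2 farthest samples, both short of the bound, so the test does not decide. The labels give no time of sampling, so it could not be tested further, and a component of stress hormone response, which moved with clock output, stays open.

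T and NK cell, B cell and neutrophil genes varied with the erythroid genes (r of 0.790, 0.700 and 0.777). A candidate explanation is blood carried in the sample: HBB had a median of 4277 CPM, no erythroid gene is in another list, no sorting step is described, and given the erythroid score the r of T and NK cells with neutrophils fell from 0.798 to 0.477, between the bounds set for and against, so that blood and another common source cannot be told apart. Immune cells of the tissue rising together stays open too: macrophage genes, which are not part of the pattern, had r = -0.114 with T and NK cells (95% interval -0.331 to 0.115), which leaves a rise of the other types possible. The tables argue against sequencing depth, with r = -0.135 (-0.350 to 0.0932) for the erythroid score. Beyond immune cells of the tissue, no biological explanation was tested.

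Genes loaded on components 1 and 2 by their transcript GC content. Across genes, which are not independent replicates, the rho of the gene correlations with GC content was 0.718 for component 1 and 0.707 for component 2, which is consistent with GC-related differences between libraries, though GC content also differs between gene groups. Red blood cell genes being rich in GC is argued against as the cause on component 1, since rho was 0.819 after removing the erythroid score. White blood cell genes were not removed, and their lists also moved with component 1 (r = 0.707 for neutrophils and monocytes, 0.651 for T and NK cells). Blood genes as a whole therefore stay open. Transcript length stays open, with rho of -0.143 and -0.243. No biological explanation was tested here either.

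Genes moved widely with the lipogenesis index, and the share of adipocytes in a sample is a candidate explanation: with the adipocyte score as covariate, 156 genes were called in place of 4869. That score had r = 0.641 with the index, so the covariate also removes part of the index itself, and a change within adipocytes stays open. GC-related library differences are argued against only as far as the GC slope measures them: 6838 genes were called with it as covariate. The index had r = 0.128 with that slope, so the covariate could remove little, and the rise in calls is not itself evidence. The lipogenesis score had r = -0.291 with component 1 and 0.510 with component 2, which both loaded by GC content. Other GC-related differences therefore stay open. Blood stays open, with 3635 genes called given the erythroid score. Beyond the share of adipocytes, no biological explanation was tested for this pattern.

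Permuted indices tested chance pairing of samples and index, and no more, for the 3 counts of called genes. Each index was taken from the expression values of these same samples, and genes co-vary. An index in its real order was therefore bound to call more genes than most permuted ones, whichever genes it held. The test shows nothing particular to macrophages, lipogenesis or leptin. The real index gave the largest count, in 1 of 101 indices, for macrophage (4835 genes, highest other 136), for lipogenesis (4869, highest other 2545) and for LEP (4644, highest other 1787). Some permuted indices thus gave large counts, although the median over them was 0 for each index, and the cause was not tested.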
